A study of Rattus norvegicus with 9 samples.

How the data were processed

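Islet RNA of 4 standard-fed and 5 cafeteria-fed rats was hybridised to the Affymetrix Rat Genome 230 2.0 array, a single-colour design, and 9 arrays were analysed here. The deposited values are intensity signals on a linear scale, 1 per probe set, made by the authors with MAS5 per the submitters' processing notes; its version and settings are not given in the sources used here. Each array's trimmed mean, with 2% cut from each end, was 500, so the values were used without further scaling. Detection calls were not used here. There is no read depth in array data, and the number of arrays limits the precision.

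Groups were taken from the sample titles; source names and descriptions say the same, and the diet characteristic says the opposite for 9 of 9 samples. Taking that field would exchange the groups and turn the sign of each difference. Each replicate is described as an independent sample.

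The 57 control probe sets were left out, leaving 31042. Gene names came from the platform annotation supplied with the values: 20826 probe sets have 1 symbol, 436 have several and 9780 have none here. Of the 20826, 20758 matched a current rat gene by identifier. Probe sets with several symbols were not named. Of 778 list members, 676 had a named probe set. The others had none named here, and whether the array has a probe set for them was not checked.

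Signals were tested as log2(signal + 16) in limma 3.58.1 (R 4.3.3) with diet as the only term, an intensity trend in the variance and Benjamini-Hochberg adjustment over the 18625 probe sets whose mean log2 signal reached the 40th percentile (a signal of about 91.1). Folds are on that scale, which understates the change of dim genes. A call needed an adjusted p under 0.05. Single values were also tested by exact permutation over the 126 splits of 4 and 5 arrays, for which the smallest two-sided p is 0.0079. Lists were tested with camera (correlation 0.01), using for each gene the probe set with the highest mean, adjusted over 32 lists, and again with an estimated correlation and fry.

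The rule for named genes, the lists and the main alternatives were fixed before the data were examined. The rule takes Sfrp5, the islet hormones Ins1, Ins2, Iapp, Gcg, Sst and Ppy, the 12 largest changes in each direction among probe sets that pass and whose groups do not overlap, filled up to 12 by the smallest unadjusted p where fewer pass, and up to 4 members per described list with the smallest unadjusted p. As none passed, all 24 were filled in that second way.

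The fit was tested on simulated data drawn from the real means and limma's estimates of spread, with 200 of 18625 probe sets changed. Probe sets were drawn independently, with the same spread in both groups. At log2 folds of 0.5, 1 and 2, 1.5%, 75.5% and 99.4% were recovered. In the list test, run on 10347 genes, 36 of 40 lists shifted by 0.2 were called, and 3 of 280 unshifted ones; the simulated genes were independent, which real genes are not.

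Alternatives were a pseudocount of 1 or 64, quantile or median normalisation, no filter or the 60th percentile, leaving out each array, the replicate number as a block, other variance models, array weights, other thresholds, 1 probe set per gene and an estimated correlation. Covariates for the beta-actin 3'/5' ratio and the cre spike, and leaving out standard replicates 1 and 3 and cafeteria replicate 3 together, were added after the arrays had been seen: the first for stress genes, the second for lymphocyte genes and the third for its beta-actin ratio. Correlations and plots used Python 3.11.15 with exact enumeration.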

Results

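Gene expression was measured in pancreatic islets of adult male Wistar rats after 30 days on standard chow, which supplied 8% of calories as fat, or on a cafeteria diet, which supplied 66%. Islets are the hormone-secreting cell clusters of the pancreas, and a cafeteria diet offers palatable, fat-rich food. The set held 9 arrays, 4 from standard-fed and 5 from cafeteria-fed rats, described in the labels as independent biological replicates. The design text names 1 more standard sample, which was not analysed here. Each array gave 1 linear signal for each of 31099 probe sets. Array medians lay between 147.0 and 166.6, and correlations between pairs of arrays between 0.941 and 0.974 over the probe sets tested. The number of arrays limits the precision of every value.

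The series title concerns Sfrp5, a secreted Wnt antagonist, in obesity. The Sfrp5 signal was 188.6 ± 14.0 (SD, n = 4) in standard islets and 82.0 ± 69.1 (SD, n = 5) in cafeteria islets. The log2 fold of cafeteria over standard was -1.35 with a standard error of 0.42. The signal was lower than on all standard arrays in 4 of 5 cafeteria arrays; cafeteria replicate 1, at 192.2, lay within the standard range. Groups follow the sample titles. The diet field of the labels says the opposite for 9 of 9 samples, and following it would turn every sign given here while leaving sizes and p-values as they are. The single Sfrp5 difference had an exact two-sided permutation p of 0.0397 over all splits of the arrays into 4 and 5. It did not pass limma's test over all probe sets, where its adjusted p was 0.839, nor the test adjusted over the list alone, that of Wnt genes, where its adjusted p was 0.0887. The signal of this 1 probe set lies at the 43rd percentile of mean signal, so it is a dim one, and whether the gene was chosen by the study from these arrays is not given in the sources used here.

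**Figure D1:**
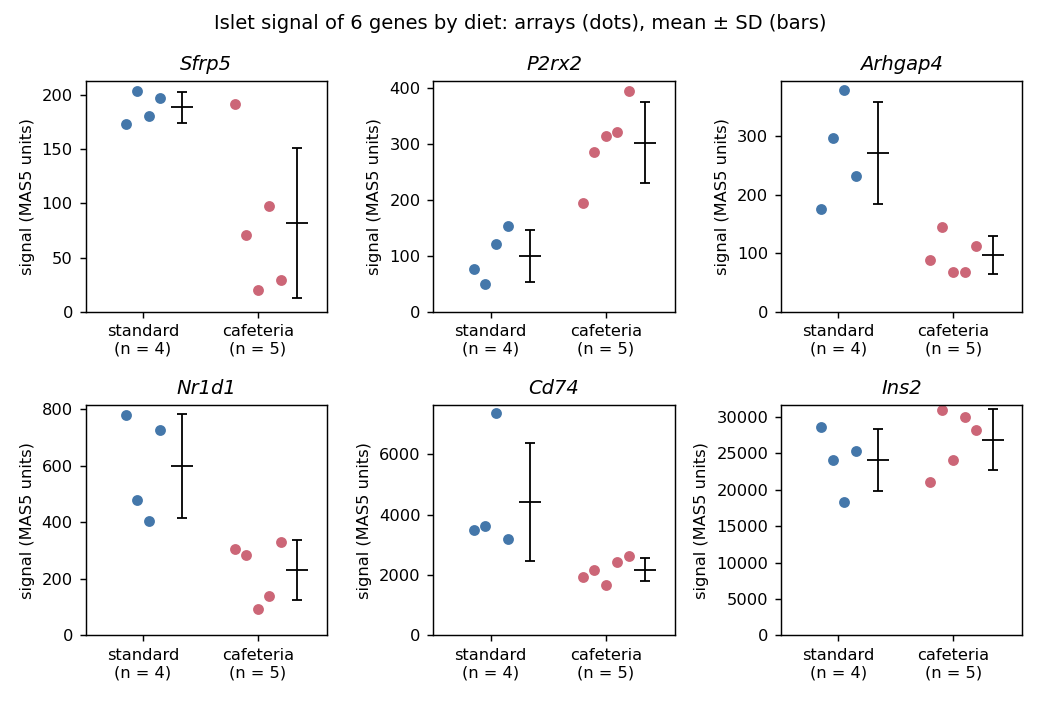
Signal of 6 genes (MAS5 units, vertical axes from 0) on each array of standard (blue, n = 4) and cafeteria (red, n = 5) islets, with mean ± SD beside the dots. The 4 lower cafeteria values of Sfrp5 lie below all standard arrays and 1 does not, while the 2 groups overlap for Ins2.

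The islet hormone genes differed by less than the spread between arrays. The insulin genes Ins1 and Ins2 had log2 folds of 0.09 ± 0.16 (SE) and 0.16 ± 0.14. Iapp, which encodes the co-secreted amyloid peptide, had 0.11 ± 0.13. Glucagon (Gcg) had 0.06 ± 0.13, somatostatin (Sst) -0.15 ± 0.16 and pancreatic polypeptide (Ppy) -0.07 ± 0.16. None passed limma's test (lowest adjusted p = 0.875). The signs of Ins1, Gcg, Sst and Ppy turned in some alternative settings, and without standard replicate 3 Ins2 had 0.037 and Iapp 0.011. Group means of these signals lay between 24082 and 44664, near the top of the scale, as the highest signal of an array was 46683 to 72297. Whether signals this high can show a difference in full was not tested, so the small folds do not exclude one.

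The first question over all genes was which were altered by the diet. No probe set passed limma's adjusted threshold of 0.05 among the 18625 tested; the lowest adjusted p was 0.228. At an unadjusted p under 0.05 there were 1080 (560 higher and 520 lower in cafeteria islets), against 931 expected on average by chance. Of 100 splits drawn from those of the 9 arrays, the real one included, 26 gave as many, and the highest other gave 3816. The real count was 711 without standard replicate 3, 1674 without standard replicate 1 and 1655 without cafeteria replicate 1. Groups did not overlap for 328 probe sets, 1.76% of those tested, where chance gives 1.59%. Diet accounted for 13.8% of the total variance, and 32 splits of the arrays into 4 and 5, the real one included, gave as much or more (exact one-sided permutation p = 0.254). In simulated arrays with limma's estimates of spread, 75.5% of changed probe sets were recovered at a log2 fold of 1 and 1.5% at 0.5. Small changes were therefore hardly detectable with 9 arrays. The simulated probe sets were independent and had the same spread in both groups, so the shares on real arrays may differ.

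The genes with the smallest p in each direction did not pass and are given as values. Among the higher ones, P2rx2, an ATP-gated channel, had a signal of 100.5 ± 46.5 (SD, n = 4) against 302.7 ± 72.6 (n = 5), a log2 fold of 1.51 ± 0.28 (SE). Dnajb11, an endoplasmic reticulum chaperone, had 0.73 ± 0.18, and Ghr, the growth hormone receptor, 0.45 ± 0.12. The clock repressor Cry1 had 0.82 ± 0.21. The others were Lrrc59 (0.56), Stxbp2 (0.61), Cyth3 (0.70), Pros1 (0.51), Rrp12 (0.81), Ppa1 (0.88), Tmem39a (0.42) and Ufm1 (0.44). Among the lower ones, the signal of Arhgap4 was 271.1 ± 87.5 against 96.6 ± 32.9, a log2 fold of -1.35 ± 0.26. Plac8 had a signal of 874.8 ± 640.1 against 162.8 ± 42.4. Ighvl1, an immunoglobulin heavy chain gene, had -2.42 ± 0.62, and Cd74, the MHC class II invariant chain, -0.95 ± 0.22. The nuclear receptors of the clock, Nr1d1 and Nr1d2, had -1.40 ± 0.33 and -0.66 ± 0.17. The others were Tmem176b (-0.55), Cyba (-0.73), Rgs4 (-0.39), Plpp3 (-0.61), Dcakd (-0.53) and Traf5 (-0.59). Their adjusted p-values by limma lay between 0.564 and 0.839. The array standard replicate 3 carried the highest Ighvl1 and Cd74 signals of its group, at 1489 and 7348.

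Of 32 gene lists fixed before the data were examined, camera, at a preset correlation of 0.01, called 13: 6 higher and 7 lower in cafeteria islets. None was called with an estimated correlation, where the lowest adjusted p was 0.332, and none by fry, where it was 0.229. Without 3 arrays doubted after their values were seen, the count was 4, without cafeteria replicate 5 it was 8, and with the filter at the 60th percentile it was 7.

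**Figure D2:**
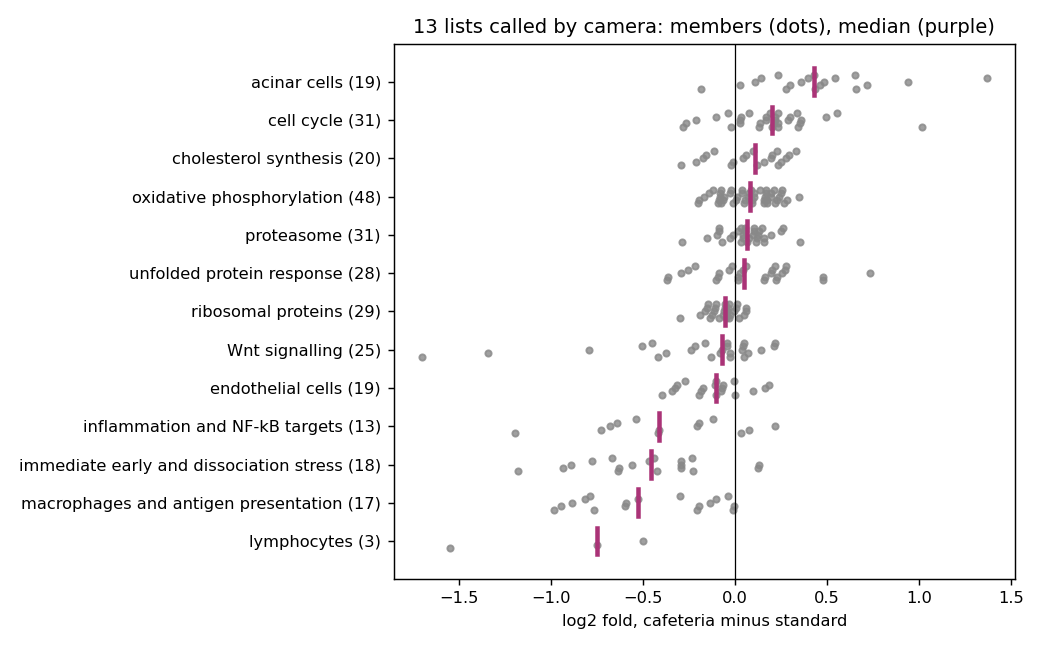
Log2 fold of cafeteria over standard islets for each tested member (grey dots) of the 13 lists camera called, with the number of genes tested in parentheses and the median as a purple line. Macrophage and antigen presentation genes all lie below 0, and 18 of 19 acinar genes above it.

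The list of macrophage and antigen presentation genes was lower. Of its 23 genes named on the array, 17 passed the filter and were tested, and 17 of 17 had a negative log2 fold. The median was -0.53 (camera adjusted p = 7.1e-06, and 0.332 with an estimated correlation). The exact permutation p of its mean difference was 0.0397, two-sided and not adjusted over the lists. 1 member passed adjusted over the list alone, Cd74, and none over all genes. RT1-Da and RT1-Db1, which are MHC class II genes, had -0.79 ± 0.26 and -0.82 ± 0.30, and the complement gene C1qc -0.59 ± 0.23. At the preset correlation camera called it in 21 of 21 alternatives, with a median of -0.22 without standard replicate 3. The lymphocyte list, with 3 of 13 named genes tested, had a median of -0.75 (camera adjusted p = 0.0055, and 0.332 with an estimated correlation). Coro1a, an actin regulator of leukocytes, had -1.55 ± 0.49 and passed adjusted over the list alone; Lck and Cd5 had -0.50 and -0.75. On standard replicate 3 the Coro1a signal was 1111, and without that array the folds of Coro1a, Lck and Cd5 were -0.93, -0.17 and -0.46; Cd5 had -0.50 without cafeteria replicate 3. The mean difference of the list was then -0.52 in place of -0.93, with an exact permutation p of 0.0536 in place of 0.0159, neither adjusted over the lists. Both used the 3 genes that passed the filter with standard replicate 3 included, so the choice of genes still depends on that array. The list's call ended at the 60th percentile filter (adjusted p = 0.216) and without the 3 doubted arrays (median -0.30, adjusted p = 0.148). Inflammation and NF-kB targets had a median of -0.41 (10 of 13 lower, camera adjusted p = 0.0055; 0.332 with an estimated correlation). Nfkbia, an NF-kB inhibitor, had -0.54 ± 0.20, Icam1 -0.68 ± 0.25, Cxcl10 -0.64 ± 0.24 and Tnfaip3 -0.42 ± 0.18. At the 60th percentile filter the call ended and the median turned to 0.030 (adjusted p = 0.584). It also ended without the 3 doubted arrays (-0.20, adjusted p = 0.270), and the median was -0.205 without cafeteria replicate 5, -0.24 without standard replicate 1 and -0.27 without cafeteria replicate 3.

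Immediate early and dissociation stress genes had a median of -0.46 (16 of 18 lower, camera adjusted p = 2.6e-05; 0.482 with an estimated correlation). Zfp36 had -0.78 ± 0.27, Ier2 -0.63 ± 0.24, Ier5 -0.42 ± 0.17 and Junb -0.90 ± 0.39 (-0.53 without cafeteria replicate 3). The call ended without standard replicate 1, with a median of -0.18 and an adjusted p of 0.174, and without the 3 doubted arrays (-0.068, 0.691); without standard replicate 4 the median was -0.70. The exact permutation p of the mean difference was 0.214.

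Acinar genes, which mark exocrine tissue around islets, were higher in 18 of 19 cases, with a median of 0.43 (camera adjusted p = 0.00071; 0.529 with an estimated correlation). Cela3b, an elastase, had 1.37 ± 0.45, Ctrb1 0.94 ± 0.39, Cel 0.66 ± 0.32 and Gp2 0.54 ± 0.29 (0.33 without cafeteria replicate 4). The exact permutation p of the mean difference was 0.333. The call ended without cafeteria replicate 1 (median 0.32, adjusted p = 0.0501). The median was 0.24 without standard replicate 4 and 0.75 without cafeteria replicate 5, the array with the lowest mean of these genes in its group; without the latter the mean difference was 0.76 (exact permutation p = 0.0857). Cell cycle genes were higher in 25 of 31 cases with a median of 0.20 (camera adjusted p = 0.0077; 0.529 with an estimated correlation). Kif20a, a mitotic kinesin, had 1.02 ± 0.29, Rrm1 0.55 ± 0.25, Ccne1 0.50 ± 0.23 and Cenpf 0.36 ± 0.18. The call ended without standard replicate 4 (median 0.10) or cafeteria replicate 5 (0.085), and at the 60th percentile filter (0.077, adjusted p = 0.541); without standard replicate 2 the median was 0.13.

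Unfolded protein response genes had a median of 0.05 (18 of 28 higher, camera adjusted p = 0.018; 0.337 with an estimated correlation). Dnajb11 passed adjusted over the list alone; Creld2 had 0.48 ± 0.17, Dnajb9 0.27 ± 0.10 and Edem1 0.48 ± 0.22. The call ended without cafeteria replicate 5 (median 0.081), with quantile normalisation (0.026) and without the 3 doubted arrays (0.096). The median was 0.112, 0.104 and 0.091 without standard replicates 1, 2 and 3, and 0.098 without cafeteria replicate 3. Oxidative phosphorylation genes had a median of 0.08 (32 of 48 higher, adjusted p = 0.0047; 0.332 with an estimated correlation), among them Ndufb6 (0.25), Cox7c (0.21), Cox7b (0.27) and Ndufb3 (0.23). With quantile normalisation that call ended (median 0.044, adjusted p = 0.0817). Proteasome genes had a median of 0.07 (23 of 31 higher, adjusted p = 0.045; 0.482 with an estimated correlation). Psmd14 had 0.35, Psma6 0.20, Psma3 0.25 and Psme1 -0.29. Cholesterol synthesis genes had a median of 0.11 (13 of 20 higher, adjusted p = 0.048; 0.332 with an estimated correlation), with Dhcr7 at 0.29, Fdps at 0.23, Msmo1 at 0.33 (0.19 without cafeteria replicate 3) and Idi1 at 0.23. The proteasome call ended without standard replicates 3 or 4 or cafeteria replicates 1 or 5 (median 0.037 to 0.071), and the cholesterol call without standard replicates 1 or 4 or cafeteria replicates 1, 3, 4 or 5 (0.065 to 0.108). The proteasome median was 0.108 without standard replicate 1, and the cholesterol median 0.165 without standard replicate 3. At the preset correlation they held in 11 and 9 of 21 alternatives.

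Wnt signalling genes had a median of -0.07 and a mean of -0.23 (17 of 25 lower, camera adjusted p = 0.027; 0.332 with an estimated correlation). Tcf7, a transcription factor that T cells also express, had -1.70 ± 0.52, and -1.04 without standard replicate 3; Sfrp5 had -1.35, and -1.36 without that array. Lrp5, a Wnt co-receptor, had -0.79 ± 0.28 and Axin1 -0.38 ± 0.14. On standard replicate 3 the Tcf7 signal was 1079. Without that array the call ended (median -0.08), as it did without cafeteria replicate 1 (-0.072). It also ended with no filter (adjusted p = 0.145), at the 60th percentile filter (median -0.028, adjusted p = 0.657), with the spike covariate (-0.039, 0.0557) and without the 3 doubted arrays (0.0827). The exact permutation p of the mean difference was 0.0079, 0.032 without Tcf7, and 0.0714 without both Tcf7 and standard replicate 3. Sfrp5 stayed in the list each time, so whether the rest of the list differs without it was not tested. These exact p-values, like those of the other lists' mean differences, were not adjusted over the lists. The median was -0.18 without standard replicate 1. Endothelial genes had a median of -0.11 (15 of 19 lower, adjusted p = 0.045; 0.482 with an estimated correlation), with Esm1 at -0.40, Pecam1 at -0.32, Nos3 at -0.34 and Tie1 at -0.33 (-0.21 without standard replicate 3). Ribosomal protein genes had -0.06 (23 of 29 lower, adjusted p = 0.045; 0.736 with an estimated correlation), with Rpl14 at -0.30, Rpl22 at -0.16, Rpl23 at -0.14 and Rps28 at -0.15; without cafeteria replicate 3, Rpl14 had -0.197, Rpl23 -0.088 and Rps28 -0.065. The endothelial call ended without standard replicates 1, 3 or 4 or cafeteria replicates 1, 4 or 5 (median -0.058 to -0.115), and the median was -0.162 without cafeteria replicate 2. The ribosomal call ended without standard replicates 1 or 2 or cafeteria replicates 3 or 4, with medians from -0.062 to 0.013, and the median was -0.090 without standard replicate 3 or cafeteria replicate 1 and -0.085 without cafeteria replicate 2. At the preset correlation these calls held in 9 and 11 of 21 alternatives.

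Genes of the circadian clock, the feedback loop that sets daily rhythms, moved apart in both directions, so that the list's median was only -0.11 (camera adjusted p = 0.214). The median was -0.21 without cafeteria replicate 1 and -0.046 without cafeteria replicate 3. Adjusted over the list alone, 6 of 14 passed, and none over all genes. Nr1d1, Nr1d2, Tef and Dbp were lower, at log2 folds of -1.40, -0.66, -0.38 and -0.64, and Cry1 and Per2 were higher, at 0.82 and 0.65 ± 0.20. Tef and Dbp, which drive output genes of the clock, were named after their values were seen. Bmal1, a core activator also named after its value was seen, had -0.08 ± 0.17. In fry's test of change in either direction the clock list had an adjusted p of 0.0116, the only one of the 32 lists under 0.05. That p was above 0.05 without standard replicates 1 or 2 (0.0753 and 0.0809) or cafeteria replicates 4 or 5 (0.143 and 0.0551), and 0.374 without the 3 doubted arrays. The log2 folds without those 3 arrays were -1.18 for Nr1d1, -0.53 for Nr1d2, 0.65 for Cry1 and 0.47 for Per2, and fewer arrays entered that test.

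**Figure D3:**
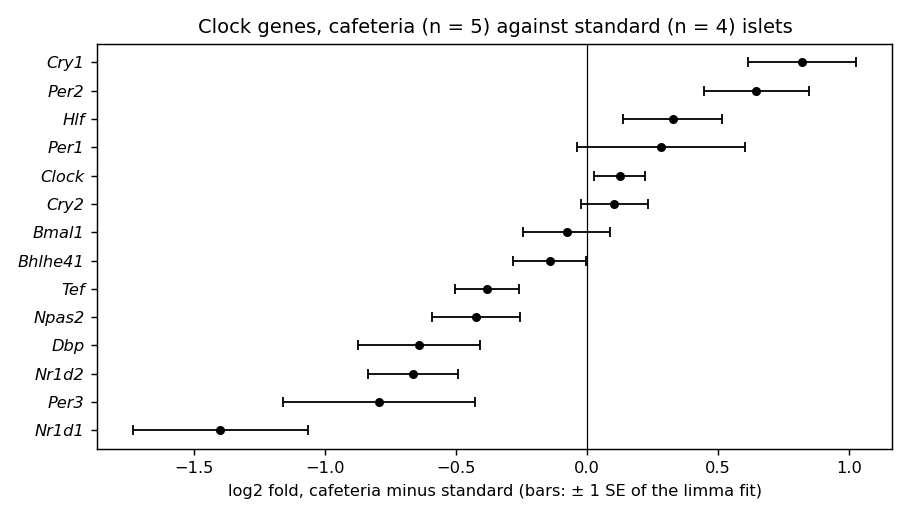
Log2 fold of cafeteria over standard islets (horizontal axis) for the 14 tested clock genes, with bars of ± 1 standard error of the limma fit. Nr1d1, at -1.40, and Cry1, at 0.82, lie at the ends.

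The other lists were not called in the main setting. At the preset correlation camera called 7 of them in some of the 21 alternatives. Other endocrine cells were called in 6, with the spike covariate (adjusted p = 0.0082), with quantile normalisation (0.0208) and without standard replicates 3 (0.0092) or 4 (0.0269) or cafeteria replicates 1 (0.0327) or 2 (0.0259). Duct cells were called in 4, without standard replicates 3 (0.0168) or 4 (0.0215), with the spike covariate (0.0192) and at the 60th percentile filter (0.0472). Genes normally silent in beta cells were called without standard replicate 4 (0.0269) or cafeteria replicate 3 (0.0461). The interferon list was called without standard replicate 2 (0.0404), fibroblasts without cafeteria replicate 1 (0.0194), Schwann cells without standard replicate 1 (0.0442), and the hypoxia list with no filter (0.0456). In the main setting the mean difference of the hypoxia list had an exact permutation p of 0.0159, not adjusted over the lists. Beta cell identity genes had a median of 0.04 (10 of 19 higher, camera adjusted p = 0.870, with median and test opposite in sign). That median lay between 0.0052 and 0.050 with each array left out. Isl1, an islet transcription factor, had -0.40 ± 0.19, Gipr -0.37 ± 0.19 (-0.20 without cafeteria replicate 3), Ero1b 0.23 ± 0.15 (0.11 without standard replicate 2) and Glp1r -0.19 ± 0.13 (-0.11 without standard replicate 4). Other endocrine cell genes had -0.18 (10 of 12 lower, adjusted p = 0.0685). Their median was -0.30 without cafeteria replicate 1, but -0.068 without cafeteria replicate 3 (adjusted p = 0.245), -0.10 without cafeteria replicate 5 (0.185), -0.097 without standard replicate 1 (0.930) and -0.022 without the 3 doubted arrays (0.979). Fatty acid oxidation and PPAR targets had 0.01 (adjusted p = 0.845), with Acot2 at -0.32, Ppargc1a, a regulator of mitochondrial genes, at 0.51, Ucp2 at -0.38 (-0.19 without cafeteria replicate 3 and -0.58 without standard replicate 1) and Slc25a20 at 0.17. Medians of the remaining lists were 0.05 for hormone granules and exocytosis, 0.06 for G1 regulators, 0.007 for fatty acid synthesis, 0.05 for glycolysis, -0.21 for genes normally silent in beta cells, -0.10 for the interferon response and -0.05 for the hypoxia response. They were -0.07 for the antioxidant response, -0.03 for insulin and IGF signalling, 0.02 for prolactin receptor targets, -0.13 for duct cells and 0.05 for fibroblasts and stellate cells. They were -0.21 for Schwann cells and neurons, 0.02 for adipocytes (opposite in sign to its test) and 0.06 for erythrocytes. Camera's adjusted p-values for these lay between 0.114 and 0.870. With each array left out, medians ranged from 0.0029 to 0.083 for hormone granules, 0.025 to 0.094 for G1 regulators and -0.26 to -0.11 for silent genes. Ranges were -0.16 to -0.039 for interferon, -0.10 to -0.052 for hypoxia, -0.11 to -0.0080 for antioxidant and -0.32 to -0.091 for Schwann cell genes.

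Readings of RNA integrity were compared because arrays differ in it. The beta-actin 3'/5' ratio, which rises when RNA is degraded, was 3.75 ± 0.80 (SD, n = 4) in standard and 4.00 ± 1.13 (n = 5) in cafeteria arrays (exact permutation p = 0.738). The first principal component, with 28.9% of the variance, followed it with r = -0.83 across the 9 arrays (exact permutation p = 0.0072; adjusted over 3 relations, 0.0217) and a Spearman rank correlation of -0.68 (exact p = 0.0503). Without the 2 arrays farthest from the median, r was -0.68 (exact p = 0.0929), so the relation rests partly on those arrays. The component's relations to the GAPDH 3'/5' ratio (r = -0.43, rank correlation -0.35) and to the cre hybridisation spike (r = -0.51, rank correlation -0.30) had exact p-values of r of 0.240 and 0.162, both 0.240 when adjusted. Groups are too small for correlations within each.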

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

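The weighing tests in this part were chosen after the results they bear on had been seen, as were the gene classes they use.

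Among 248 groups of arrays examined, 17 had an array set apart from the rest by Dixon's gap over range, where chance gives about 12.4. Of these, 6 were on standard replicate 3. It was the highest of its group for Cd74 (gap over range 0.853), Ighvl1 (0.927), RT1-Da (0.833), Coro1a (0.848) and the macrophage and antigen presentation list (0.842), and the lowest for Per2 (0.899). Standard replicate 1 was highest for Sst (0.881) and lowest for Ucp2 (0.915). Cafeteria replicate 5 was lowest for Tmem39a (0.777), Icam1 (0.733) and Cel (0.837). Cafeteria replicate 3 was highest for Acot2 (0.756) and lowest for the oxidative phosphorylation list (0.857) and the antioxidant list (0.827). Cafeteria replicate 2 was highest for Ier2 (0.852) and the stress list (0.733), and cafeteria replicate 1 for Axin1 (0.792).

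The macrophage and antigen presentation list was called lower in cafeteria islets by camera at the preset correlation. It was not called with an estimated correlation (adjusted p = 0.332) or by fry (adjusted p = 0.229). Standard replicate 3 stood apart in this list. Without that array the mean log2 difference of the macrophage and antigen presentation list was -0.29 in place of -0.47, with an exact p of 0.125 over 56 splits, so lymphoid tissue carried over on that array could account for part of the difference and remains open. Macrophage genes (mean difference -0.22) were less reduced than MHC class II genes (-0.77), with an exact p of 0.0476, but of 0.179 without standard replicate 3, so fewer macrophages in the cafeteria preparations remain open too. An effect of the diet on immune cells was not separated from these.

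Sfrp5 was lower in cafeteria islets. With the beta-actin 3'/5' ratio as a covariate its log2 fold was -1.22 ± 0.28 (SE). Among cafeteria arrays, however, the signal fell as the ratio rose, from 192.2 at 2.79 (replicate 1) to 20.3 at 5.63 (replicate 3). On standard arrays it stayed between 173.0 and 203.5 at ratios of 3.00 to 4.84. The covariate has 1 slope for both groups and cannot test a relation seen in 1 group, so RNA integrity remains open for Sfrp5. The weakest fold with 1 array left out was -1.06 ± 0.38, which argues against a single array. A chance split stays open: the exact p was 0.0397, but limma's adjusted p was 0.839, and the gene may have been picked from these arrays.

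Clock genes lay apart between the diets in both directions. With the beta-actin covariate fry's adjusted p for change in either direction was 0.0194. This argues only against a relation to that ratio shared by both groups as the whole cause. The covariate has 1 slope for both groups, so RNA integrity otherwise remains open here, as for Sfrp5. Over all alternatives fry's adjusted p ranged from 0.0013 to 0.374, the highest without the 3 doubted arrays. The exact one-sided p of the summed squared differences was 0.0159, and 0.254 adjusted over 32 lists, so chance is not excluded. Islets taken at another time of day in the 2 groups could give such a pattern, as could a diet effect on the clock; the hour of collection is not given in the sources used here, so these cannot be told apart. An exact p of 0.0238 for late-peaking against early-peaking genes decides nothing, since the classes were set after the folds were seen.

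Of 100 splits drawn from those of the 9 arrays, the real one included, only the real one gave as many as 13 called lists, and the highest other split gave 12. This gives 1 of 100 for the count of called lists, by a margin of 1 list. The other splits called a median of 5 lists, so camera at the preset correlation also called lists in groupings that do not follow diet. Splits that were not drawn could also reach 13, so chance is made less likely for this count but is not excluded. In 4 of the 13 lists camera's adjusted p was 0.045 to 0.048, and no list was called with an estimated correlation. Without cafeteria replicate 5 the count was 8. Of the 99 other splits, 12 reached that count, but with all 9 arrays in the fit, so this does not measure chance for it. For probe sets called, the real count is 0, which all 100 of 100 splits must reach, so this comparison says nothing about chance; the highest other split called 158. At an unadjusted p under 0.05, 26 of 100 splits gave as many as the real 1080, and the highest other 3816, so chance is not excluded there. The split with 158, with standard replicate 1 and cafeteria replicates 3, 4 and 5 on one side, points to a structure of the arrays that does not follow diet.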

How the results depend on the processing

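The RNA integrity and spike covariates and the joint removal of 3 arrays were chosen after the data were seen. Limma called 0 probe sets in each setting except without standard replicate 2, where it called 2, both lower and both without a gene name here (range over arrays left out 0 to 2); at an unadjusted p under 0.05 the count ranged from 587 to 1821. Sfrp5 kept its direction in 22 of 22 alternatives, between -0.91 and -1.69, and passed limma's test in none; the 60th percentile filter removes it, so its value there comes from the unfiltered fit. The count of called lists was 13, and 7 with the filter at the 60th percentile, 8 with the replicate number as a block, 4 without 3 doubted arrays, 0 with an estimated correlation and 8 to 14 with each array left out. Causes were not tested. The block also leaves out cafeteria replicate 5, and without that array alone the count is 8 too. With the block, fry's adjusted p for clock change in either direction was 0.0686, and camera's adjusted p was 0.109 for the cell cycle, 0.0922 for the unfolded protein response, 0.143 for the proteasome, 0.0868 for cholesterol synthesis and 0.0713 for endothelial cells. Replicate numbers do not pair the samples: correlations of deviations were -0.38, -0.05, -0.12 and 0.03. The separation of the groups ranged from 13.1% to 18.4% and passed in no setting run; it was not run with the block, the covariates or the variance models, and camera has no robust option.

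Of 1914 values of named genes other than Sfrp5, 1901 kept their direction and 13 reversed. All 13 were values of the hormone genes Ins1, Gcg, Sst and Ppy, which were named in advance. The genes other than the hormones were chosen by a small p in these same arrays, so keeping their direction says little about stability. No named gene passed the adjusted threshold in any setting, so staying on its side says nothing about stability either. With each array left out, Ins1 ranged from -0.057 to 0.17, Gcg from -0.017 to 0.16, Sst from -0.24 to 0.0041 and Ppy from -0.18 to 0.036. Of 87 genes, 21 moved by over 1.5 times with 1 array left out, including 11 without cafeteria replicate 3 and 10 without standard replicate 3, with some genes moved by several arrays. Ins1 was -0.0019 and Gcg -0.014 with the spike covariate, Gcg -0.012 with quantile normalisation, Ppy 0.044 with array weights, and Sst 0.048 and Ppy 0.035 without the 3 doubted arrays.

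Of 672 list medians, 41 reversed. Without the 3 doubted arrays these were G1 regulators (-0.0066), fatty acid synthesis (-0.075), glycolysis (-0.050), antioxidant response (0.061), insulin and IGF signalling (0.0061), ribosomal proteins (0.047), fibroblasts and stellate cells (-0.031) and erythrocytes (-0.17). With quantile normalisation they were fatty acid synthesis (-0.018) and fatty acid oxidation (-0.0047); with equal medians insulin and IGF signalling (0.0056); with no filter fatty acid synthesis (-0.013); and at the 60th percentile inflammation (0.030) and the clock (0.014). Array weights reversed fatty acid synthesis (-0.015), insulin and IGF signalling (0.045) and adipocytes (-0.056); with the block adipocytes (-0.049) and erythrocytes (-0.195) reversed, with the same medians without cafeteria replicate 5 alone; the spike covariate reversed beta cell identity (-0.0019). With each array left out, medians ranged from -0.027 to 0.041 for fatty acid synthesis, -0.012 to 0.073 for glycolysis, -0.068 to 0.051 for insulin and IGF signalling, -0.048 to 0.16 for prolactin receptor targets, -0.090 to 0.013 for ribosomal proteins, -0.22 to 0.057 for duct cells, -0.0083 to 0.13 for fibroblasts, -0.076 to 0.078 for adipocytes and -0.195 to 0.32 for erythrocytes.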

Other observations

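A pair of probe sets without a gene name here had the lowest p-values of all. The first had a signal of 924.2 ± 731.2 (SD, n = 4) in standard and 38.0 ± 36.3 (n = 5) in cafeteria islets, a log2 fold of -3.90. The second had 600.4 ± 512.8 and 63.6 ± 18.1, a log2 fold of -2.60. The 2 diet groups did not overlap for either, with an exact permutation p of 0.0079, the smallest these splits can give, and neither passed limma's test (adjusted p = 0.228 and 0.481). Without standard replicate 2 both passed, with log2 folds of -4.41 and -3.08 and an adjusted p of 0.0273 for each by limma. That array had the lowest standard signal for both (220.8 and 160.2), so leaving it out had to enlarge the difference. Standard replicate 3 had the highest for both (1686 and 1331). The other pair of unnamed probe sets shown had log2 folds of 0.97 and 0.76, higher in cafeteria islets. These probe sets were chosen after their values were seen.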
